A study of Mus musculus with 2 samples.

How the data were processed

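MicroRNA-seq libraries from heart tissue of aged female B6CASTF1/J mice were analysed, with 2 samples in 1 group. Per the labels' protocols, libraries were made from total RNA with a multiplexed microRNA protocol, of which the labels give only a link. The authors deposited raw counts per microRNA gene for each library, in 3 columns for reads on either strand, on the sense strand and on the antisense strand, per the values of the files, since they have no headers. Per the readme text deposited with each library, the assembly was mm10 and the annotation GENCODE M21, and each table came from 1 read file. The aligner, the counter and their settings are not given in the sources used here. Each file also holds 4 rows that are no genes, for unmapped, multimapping, featureless and ambiguous reads, and these were kept out of library sizes and tests. They took 14.9%, 43.9%, 5.07% and 0% of the reads of replicate 1 in the sense column, and 16.2%, 43.2%, 5.75% and 0% of those of replicate 2. A read that maps to more than 1 locus enters no gene count, which lowers genes whose mature sequence is encoded at several loci, and a count per hairpin gene does not separate the 2 arms of a hairpin.

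All 2202 gene identifiers were matched to GENCODE M21, which gave symbols, positions in mm10, host genes and genes on the opposite strand. Hairpin sequences of the same annotation were compared with each other, and a gene was taken to share a stretch when 20 nt or more recurred at another locus, which held for 1087 genes. The strand-specific column with the larger total, the sense column, was the main one. Its totals were 3383676 and 3676084 counts, so that 3 counts correspond to 0.887 and 0.816 CPM. CPM was computed on these totals. A gene was detected at 10 counts or more in each library.

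The libraries form 1 group, so no test between groups was made. Means and SDs are over n = 2. The 2 libraries were compared per gene with a two-sided exact binomial test on sense counts, with the expected share from TMM effective library sizes and Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation is the square root of the common dispersion of edgeR 4.0.16 in an intercept-only design, with an interval from resampled genes. DESeq2 1.42.0 gave alternative size factors and a median gene-wise dispersion. The software was R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. For each list with 3 or more detected genes, the median log2 ratio was placed among 10000 random lists of the same size drawn from 10 bins of mean expression, as a description without a p-value. Random lists break up families and clusters, whose genes are not independent. Shares of a single library have Wilson 95% intervals and ratios of counts have exact 95% intervals.

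The 19 gene lists, of which 10 are cell type markers (striated muscle, smooth muscle, endothelial, fibroblast and stroma, erythroid, white blood cell, neuronal, hepatocyte, epithelial and endocrine, pluripotent cell) and 9 are families, clusters or a process, were fixed before the data were examined, and so were the alternatives and the rule for named genes. The lists hold 275 genes, 5 of them in more than 1 list. The rule names the 20 genes with the highest mean CPM, the 4 highest members of each list at 10 CPM or more, the members of 10 fixed ratios, the highest neuronal, hepatocyte, epithelial and endocrine, and pluripotent cell gene, and the 10 genes with the largest absolute log2 ratio among called genes with a mean of 100 counts or more. Other members of the striated muscle, fibroblast and stroma, epithelial and endocrine, and miR-15/16 lists, and Gm25301, Mir24-1, Mir24-2, Mir26a-1, Mir26a-2, Mir34b, Mir449a, Mir25, Mir130a, Mir106a and Mir20b, were chosen after their values were seen.

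The steps were tested on simulated data. With counts of 324 genes drawn with counting noise only, the binomial test called 80% of 45 genes changed 2-fold, 97.6% of 41 changed 4-fold and 0% of 238 unchanged genes. A simulated coefficient of variation of 0.3 over 322 genes was estimated as 0.287. A list shifted by 1 on the log2 scale among 300 genes reached percentile 99.98 and an unshifted list percentile 6.86. These simulated ratios were independent and less spread than those of the data (SD 0.955). The check thus does not show how well the percentile separates the real lists. Alternatives tried were the column for reads on either strand, the deeper library thinned to the shallower total, other minimum counts, DESeq2 size factors, library totals, other denominators of shares, lists without genes that carry a locus number, and each library left out. Of the results fixed before the data were examined, 1 is not reported here. The featureless and unmapped reads were not analysed beyond their shares, and the multimapping reads could not be assigned to genes from the files.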

Results

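MicroRNA libraries were measured from heart tissue of aged female mice of the hybrid B6CASTF1/J, the first-generation cross of C57BL/6J and CAST/EiJ. Their reads were counted on mm10, so variants of CAST/EiJ in a microRNA may lower its count, which could not be tested here. The labels give an age of 18 to 20 months, a total RNA source and a size range under 30, for which they state no unit. There was 1 group of 2 libraries, which the labels number as biological replicates with separate tissue records but 1 shared donor record. Whether the tissues came from separate animals is thus open, so each SD and coefficient of variation below measures only the spread between these 2 libraries, part of which may be technical. The binomial p-values below set these 2 libraries against counting noise alone, and the permutation p-values are taken across genes. With 1 group, the design holds no contrast between conditions. The questions it answers are which microRNA genes the aged heart yielded, and how far the 2 libraries differed.

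Replicate 1 held 9362013 reads and replicate 2 held 10549508. Reads on the sense strand of a microRNA gene numbered 3383676 in replicate 1, or 36.1% (Wilson 95% interval 36.1 to 36.2), and 3676084 in replicate 2, or 34.8% (34.8 to 34.9). Reads mapping to more than 1 place, which entered no gene count, took 43.9% (43.9 to 43.9) and 43.2% (43.2 to 43.2). Intervals and floors cover counting error only, because reads amplified by PCR without molecular identifiers are not independent molecules. Values below are counts per 1000000 sense gene counts of the library (CPM), as mean ± SD over n = 2 libraries unless 1 library is named. A gene with 0 counts has an upper limit, set by 3 counts, of 0.887 CPM in replicate 1 and 0.816 CPM in replicate 2.

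**Figure D1:**
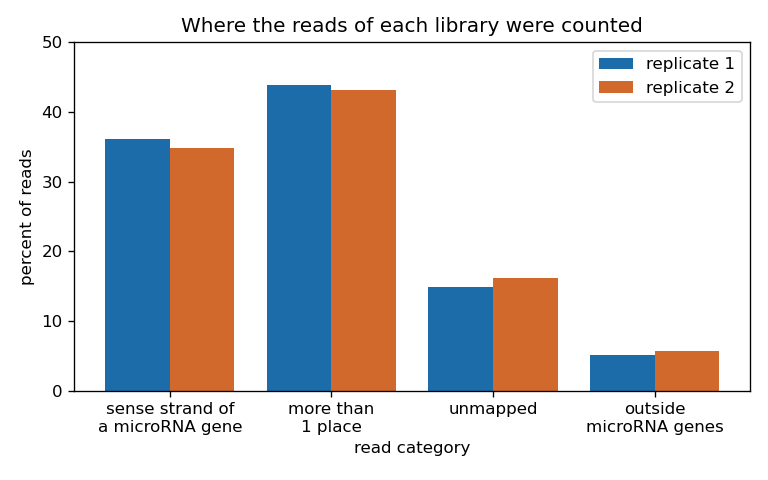
Percent of all reads of each heart library (y axis) in 4 read categories (x axis), with 1 bar per replicate. In both libraries reads mapping to more than 1 place, 43.9% and 43.2%, outnumbered the reads counted on the sense strand of a microRNA gene, 36.1% and 34.8%.

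Among reads that mapped to 1 place, the highest means in the aged heart were those of Mir378a, at 127632 ± 18692 CPM, and Mir126a, at 93379 ± 50437 CPM. Multimapping reads, at 1.22 and 1.24 per sense gene count in replicates 1 and 2, lie outside this ranking. MicroRNAs encoded at several loci may thus be missing from it. Mir378a (mm10 chromosome 18, 61397835 to 61397900) lies in an intron of Ppargc1b, the gene of a coactivator of mitochondrial metabolism. Mir126a (chromosome 2, 26591357 to 26591429) overlaps an exon of Egfl7, an endothelial gene, and is known as a microRNA of endothelial cells. Mirlet7b (67962 ± 10235 CPM), Mirlet7i (67320 ± 2816 CPM), Mir23b (64216 ± 13825 CPM), Mir23a (60975 ± 10926 CPM) and Mirlet7g (60182 ± 3380.4 CPM) followed. Mir139, in an intron of Pde2a, reached 38762 ± 5766 CPM, Mir143 reached 38667 ± 7181 CPM and Mir22 reached 32956 ± 26062 CPM. Mir126a was above Mir378a (114415 CPM) in replicate 1, but in replicate 2 it lay below Mir378a (140849), Mirlet7b, Mir23b, Mirlet7i, Mir23a and Mirlet7g. Mir126a and Mir22 lay far apart in the 2 libraries: Mir126a had 129043 CPM in replicate 1 (Wilson 95% interval 128686 to 129401) and 57714 in replicate 2 (57476 to 57953), and Mir22 had 51384 (51149 to 51619.8) and 14527 (14405 to 14650). The first 10 genes held 65.2% ± 0.368 of the counts, and the first 20 held 83.5% ± 0.907. The other 10 of those 20 were Mir26b (28864 ± 3735), Mir99a (27063 ± 6291), Mirlet7d (26529.7 ± 2335), Mir29a (26169 ± 9718), Mir30d (15694 ± 2397), Mir149 (15686 ± 4148), Mir30a (13348 ± 284), Mir191 (11486 ± 1551), Mir125a (9357 ± 3376) and Mir99b (8584 ± 45.3 CPM). The order among neighbours is not resolved: the means of Mirlet7b and Mirlet7i, for example, lie closer together than 1 SD of either. At least 10 counts in each library were reached by 316 of the 2202 annotated microRNA genes, called detected below, and 1494 genes had 0 counts in both. Of the detected genes, 73 share 20 nt or more with another microRNA locus, so that their counts are uncertain: among those named here are Mir378a, Mir23a, Mir23b, Mir27a, Mir27b, Mir29c, Mir30c-2, Mir92-1, Mir128-1, Mir138-1, Mir138-2, Mir146 and Mir411.

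**Figure D2:**
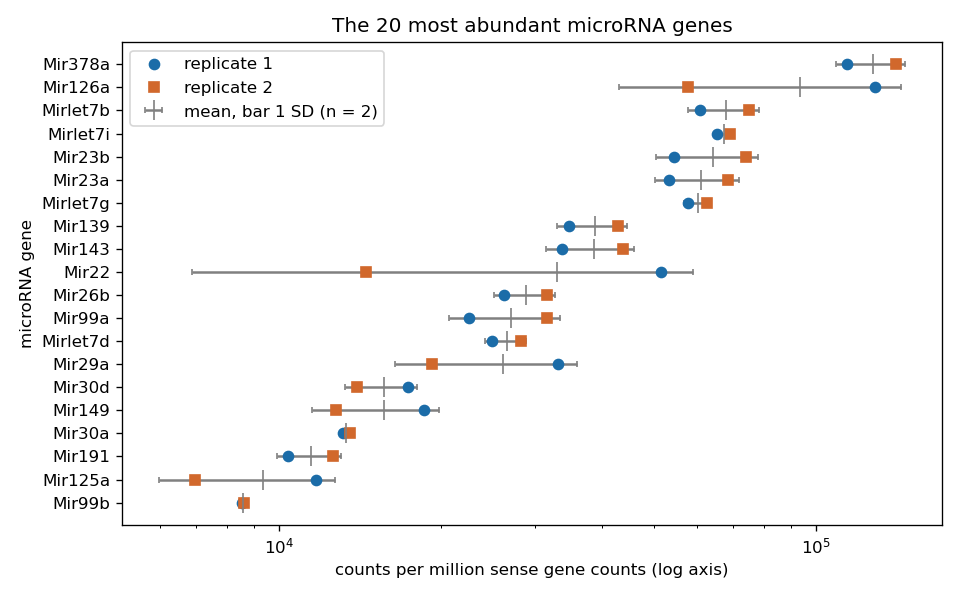
CPM on a log axis (x axis) of the 20 microRNA genes with the highest mean (y axis), with 1 symbol per replicate and a grey bar for the mean ± 1 SD (n = 2). Mir126a and Mir22 show the widest gaps between the replicates, with log2 ratios of replicate 2 over replicate 1 of -1.28 and -1.95.

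Among striated muscle microRNAs, Mir499 and Mir208a had the highest counts. Mir499, in an intron of Myh7b (chromosome 2, 155622880 to 155622958), stood at 3772 ± 289.9 CPM, and Mir208a, in an intron of Myh6, the adult cardiac myosin heavy chain gene (chromosome 14, 54949060 to 54949142), stood at 1418 ± 241 CPM. Mir208b, in an intron of Myh7, the slow and fetal cardiac isoform (chromosome 14, 54975700 to 54975776), stood at 38.1 ± 29.7 CPM. Mir208a exceeded Mir208b in both libraries, standing at 26.9 times its level in replicate 1 (exact 95% interval 23.3 to 31.1) and 72.8 times in replicate 2 (56.8 to 94.8). The classical heart microRNAs miR-1 and miR-133 were counted at low levels: Mir1a-2 at 72.0 ± 14.4 CPM, Mir1a-1 at 4.04 ± 2.64 CPM, Mir133a-2 at 5.21 ± 3.91 CPM, Mir133b at 4.89 ± 2.32 CPM and Mir133a-1 at 3.05 ± 2.23 CPM. Each of these 5 hairpins shares a stretch of 20 nt or more with another microRNA locus, so their gene counts are uncertain and are no measure of the mature microRNA. Mir206, known from skeletal muscle, stood at 10.9 ± 3.37 CPM, and Mir1b at 0.692 ± 0.560 CPM. The list of 10 genes took 0.533% ± 0.0573 of the counts. The counts of Mir1a-1 and Mir1a-2 together were 9.18 ± 0.194 times those of Mir133a-1 and Mir133a-2 (exact 95% intervals 6.46 to 13.9 and 6.02 to 14.1), a ratio that falls to 0.466 with reads on either strand and that rests on 32 and 26 counts in its denominator.

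The endothelial list, nearly all Mir126a, took 9.34% ± 5.04 of the counts, while Mir126b, on the opposite strand, had 4 counts in replicate 1 and 1 in replicate 2. Mir126a was thus 109160 times Mir126b in replicate 1 (exact 95% interval 42634 to 400638). The ratio in replicate 2 rests on 1 count of Mir126b, and its exact 95% interval begins at 38079. The smooth muscle list took 4.32% ± 1.07, with Mir143 at 11.3 ± 7.22 times Mir145a (4564 ± 3555 CPM), its neighbour in the cluster on chromosome 18. The fibroblast and stroma list took 0.602% ± 0.000319, led by Mir21a (2879 ± 1241 CPM), Mir214 (1956 ± 1783 CPM), Mir10b (1008 ± 663 CPM) and Mir152 (163 ± 122 CPM). Mir199b and Mir199a-2, which share a stretch with each other's locus, had 9.79 ± 4.23 CPM and 6.10 ± 0.157 CPM, and Mir199a-1 had 0 counts.

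Blood cell microRNAs were present in both libraries. White blood cell genes took 1.25% ± 0.546 of the counts, led by Mir150 (5041 ± 3813 CPM), known from lymphocytes, Mir155 (4574 ± 435 CPM), Mir146 (1715 ± 544 CPM) and Mir142 (946 ± 532 CPM). Erythroid genes took 0.312% ± 0.157, led by Mir451a (1247 ± 628 CPM), Mir486 (1126 ± 347 CPM) and Mir144 (687 ± 611 CPM). Mir451a was 2.33 ± 1.16 times Mir144, and Mir486 was 18.5 ± 9.07 times Mir3107, its partner on the other strand (63.8 ± 12.5 CPM). The comparison of hairpins left out overlapping loci, so whether reads could fit both Mir486 and Mir3107 was not tested. Among markers of cell types foreign to the heart, several share a stretch with another locus, so low counts there do not show that the microRNA was low. Epithelial and endocrine genes took 0.0663% ± 0.0365, with Mir203 (193 ± 173 CPM), Mir200c (172 ± 128 CPM), Mir375 (73.9 ± 83.2 CPM) and Mir215 (49.1 ± 60.6 CPM) highest. Neuronal genes took 0.0278% ± 0.000208 (0.00267% without genes that carry a locus number; 12 of the 13 genes share a stretch and 5 had 0 counts), mostly Mir128-1 (179 ± 13.3 CPM), followed by Mir138-1 (30.8 ± 7.61 CPM), Mir137 (26.7 ± 1.56 CPM) and Mir138-2 (17.9 ± 3.16 CPM). The liver microRNA gene Mir122 had 20.5 ± 4.81 CPM, or 0.00205% ± 0.000481. Pluripotent cell genes took 0.000998% ± 0.000219, and their highest member, Mir302d, had 3.87 ± 1.63 CPM.

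Of the families and clusters, let-7 took the most, 24.2% ± 1.90 of the counts. Family shares and the order of members are uncertain, since reads that fit several loci entered no count. A stretch is shared with another locus by 6 of the 14 let-7 genes and 7 of the 7 miR-23/24/27 genes. Mir16-1 and Mir16-2, for example, had 797 ± 277 CPM and 180 ± 65.8 CPM, and Mir24-1 and Mir24-2 had 79.9 ± 34.5 CPM and 157 ± 76.5 CPM. The miR-23/24/27 clusters took 13.4% ± 2.45, with Mir23b at 10.1 ± 2.54 times Mir27b (6419 ± 247 CPM) and with Mir27a at 1898 ± 77.9 CPM. The miR-30 family took 3.94% ± 0.141, with Mir30e at 8431 ± 733 CPM, Mir30c-2 at 1123 ± 30.1 CPM and a ratio of Mir30a to Mir30e of 1.59 ± 0.104. The miR-29 family took 2.77% ± 1.04: Mir29a was 18.7 ± 1.72 times Mir29c (1429 ± 651 CPM), while Mir29b-1 and Mir29b-2, of which both share a stretch with another locus, had 40.6 ± 1.57 CPM and 32.4 ± 8.91 CPM. The miR-15/16 family took 1.43% ± 0.766, led by Mir15b (4369.5 ± 2781 CPM), Mir195a (3882 ± 4161 CPM), Mir322 (3056 ± 788 CPM) and Mir15a (1421 ± 1024 CPM). The miR-17-92 cluster and its paralogs took 1.20% ± 0.109, led by Mir93 (5140.0 ± 609 CPM), Mir92-1 (2815 ± 1189.8 CPM), Mir17 (1455 ± 344 CPM) and Mir106b (828 ± 435 CPM). Mirlet7c-1 was counted at 0.319 ± 0.0207 times Mirlet7c-2, a pair that shares its mature sequence, so the ratio rests on reads that differ between the loci. The imprinted Dlk1-Dio3 cluster on chromosome 12 took 0.192% ± 0.0659, led by Mir127 (695 ± 309 CPM), Mir541 (226 ± 96.1 CPM), Mir411 (217 ± 59.2 CPM) and Mir379 (135 ± 38.0 CPM). The Sfmbt2 cluster list, of which 71 of 81 genes lie within Sfmbt2 on chromosome 2, took 0.0945% ± 0.0314, led by Mir467d (544 ± 113 CPM), Mir467e (134 ± 66.7 CPM), Mir669c (97.6 ± 43.2 CPM) and Mir669o (96.1 ± 50.3 CPM). Of these 81 genes, 79 share a stretch with another locus and 68 had 0 counts. Genes known from heart remodelling and ageing, which include Mir22, Mir23a, Mir29a and Mir195a, took 13.0% ± 2.81.

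The 2 libraries differed in many single genes. Mir126a, Mir22, Mir195a and the erythroid gene Mir144 were higher in replicate 1, with log2 ratios of replicate 2 over replicate 1 of -1.28, -1.95, -2.98 and -2.26. Mir150, Mir145a and the epithelial genes Mir375 and Mir203 were higher in replicate 2, with log2 ratios of 1.60, 1.66, 3.01 and 2.03. Mirlet7g and Mir27a were not told apart between the libraries (log2 ratios -0.01 and -0.04), although both passed under other scalings. A two-sided exact binomial test per gene on TMM-scaled counts, adjusted by Benjamini-Hochberg over 316 genes, called 191 genes at 0.05, of which 105 were higher in replicate 2 and 86 in replicate 1. This balance depends on the scaling: library totals gave 128 and 70, and DESeq2 size factors 93 and 94. The test compares these 2 libraries, not conditions, and at this depth it calls small differences: 67 of the called genes differed by 2-fold or more (32 higher in replicate 2 and 35 in replicate 1), and 246 of the 316 lay within 2-fold. The libraries differed by more than counting noise, as 2 preparations of 1 tissue could too, and they are counted as 2 samples on the labels' numbering alone. The biological coefficient of variation was 0.422 by edgeR's common dispersion (bootstrap 95% interval over genes 0.377 to 0.461). DESeq2's median of gene-wise values, a different measure, was 0.158. Scaling by library totals moved the median log2 ratio of the detected genes from 0.05 to 0.18, and DESeq2 size factors moved it to 0, so ratios near 0 have no settled sign.

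**Figure D3:**
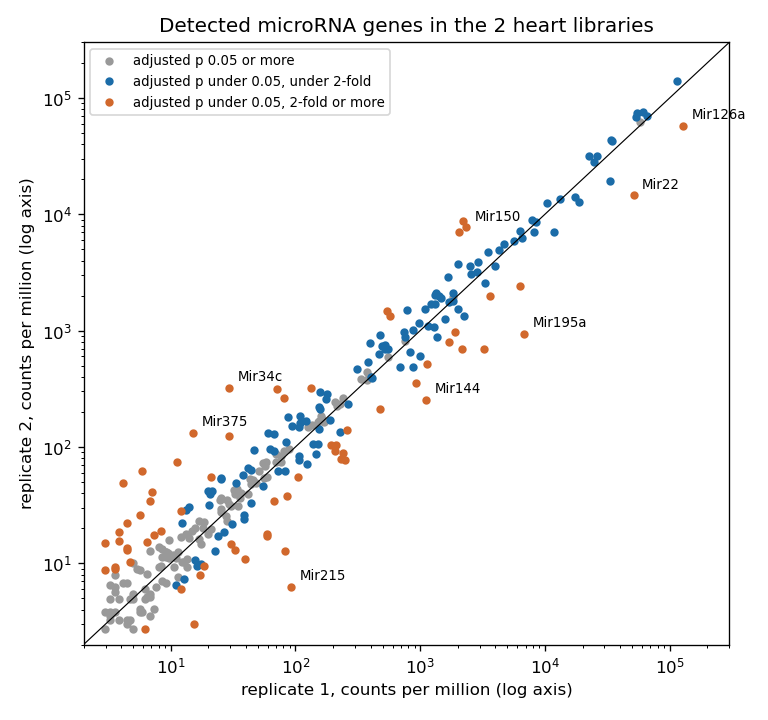
CPM of the 316 detected genes in replicate 1 (x axis) and replicate 2 (y axis), both on log axes, coloured by the exact binomial test and by fold after TMM scaling, with a line at equal CPM. Mir126a, Mir22, Mir195a, Mir144 and Mir215 lie below the line, and Mir34c, Mir375 and Mir150 lie above it.

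The 10 widest differences among called genes with a mean of 100 counts or more went both ways. Higher in replicate 1 were Mir215 (log2 ratio -4.00), Mir195a (-2.98), Mir301 (-2.80), Mir214 (-2.33) and Mir144 (-2.26). Higher in replicate 2 were Mir34c (3.33), Mir182 (3.26), Mir375 (3.01), Mir183 (2.60) and Mir203 (2.03). Mir34c, for example, had 100 counts in replicate 1 and 1188 in replicate 2 (exact binomial test, adjusted p = 4.69e-198), and Mir215 had 311 and 23 (exact binomial test, adjusted p = 4.03e-76). Genes of 1 cluster could differ: Mir145a was higher in replicate 2 by 3.17-fold while Mir143 was higher by 1.20-fold, so that Mir143 over Mir145a was 16.4 in replicate 1 and 6.18 in replicate 2.

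White blood cell genes were higher in replicate 2 and most erythroid genes higher in replicate 1. All 5 detected white blood cell genes were called higher in replicate 2 (median log2 ratio 1.09, percentile 99.9 among 10000 random lists of like expression), although Mir155 (0.07) is not called with DESeq2 size factors. Of 4 detected erythroid genes, Mir144, Mir451a (-1.20) and Mir486 (-0.76) were higher in replicate 1, and Mir3107 had a log2 ratio of 0.28 (median -0.98, percentile 1.25). Mir3107 was called higher in replicate 2 only with library totals or when adjusted over the list alone. Epithelial and endocrine genes parted: 6 were higher in replicate 2, among them Mir203, Mir200c (1.57) and Mir429 (2.42), while Mir215, Mir192 (-1.45), Mir194-1 (-1.24) and Mir194-2 (-1.16) were higher in replicate 1 (median 0.57, percentile 98.9). Of 8 detected miR-15/16 genes, 6 were higher in replicate 1 and 1, Mir322, in replicate 2 (median -0.87, percentile 0.580). The Dlk1-Dio3 cluster had 13 of 27 detected genes higher in replicate 2 and 1 lower (median 0.32, percentile 98.6), and the Sfmbt2 cluster had 6 of 6 higher (median 0.94, percentile 99.6).

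Striated muscle genes had a median log2 ratio of -0.38 (percentile 14.1), with Mir208a, Mir208b, Mir499 and Mir1a-2 higher in replicate 1 (4 of 6 detected genes). The miR-29 family had 3 of 4 genes higher in replicate 1 (median -0.80, percentile 4.59), Mir29b-1 being the exception (-0.20). Fibroblast and stroma genes split into 2 higher in replicate 2 (Mir21a and Mir10b) and 2 higher in replicate 1 (Mir214 and Mir152), with a median of 0.30 (percentile 84.2) that turns to -0.56 at 100 counts or more. The let-7 family had 6 genes higher and 3 lower in replicate 2, all within a log2 ratio of -0.35 to 0.20 (median 0.06, percentile 50.1). The miR-30 family had 1 higher and 4 lower (median -0.13, percentile 17.0), the miR-23/24/27 clusters 2 and 4 (-0.20, percentile 14.4), and the miR-17-92 clusters 5 and 5 (-0.02, percentile 33.5), whose median is -0.73 at 100 counts or more. Heart remodelling and ageing genes had 4 higher, Mir34c among them, and 6 lower, Mir195a among them (median -0.12, percentile 13.8). Neuronal genes had 1 call, Mir128-1 (-0.28), which library totals do not call, and a median percentile of 41.8. Both smooth muscle genes with 10 counts or more were higher in replicate 2, and Mir126a, the only detected endothelial gene, in replicate 1. Mir122, the only hepatocyte gene, was lower (-0.61; exact binomial test, adjusted p = 0.0209), a call that library totals do not give, and no pluripotent cell gene was called. The medians of the miR-17-92, neuronal and remodelling lists turn above 0 with library totals, and that of the miR-23/24/27 clusters turns to 0.10 with reads on either strand. Counts adjusted over the list alone equalled those over all genes in 17 of the 19 lists: the exceptions were 1 erythroid gene higher in replicate 2 instead of 0, and 3 fibroblast and stroma genes instead of 2.

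**Figure D4:**
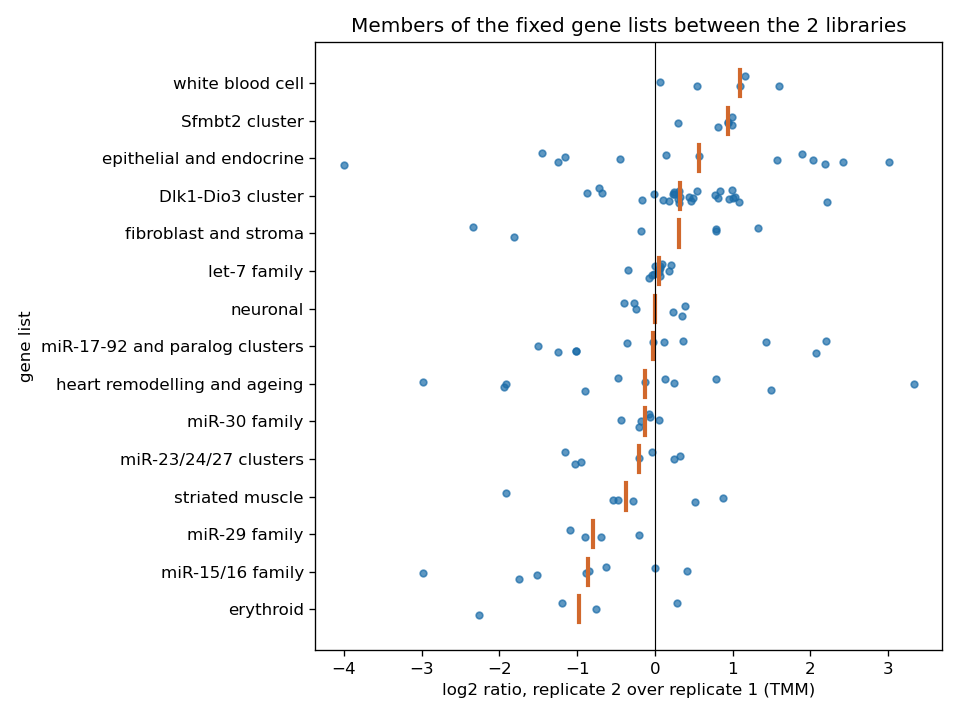
Log2 ratio of replicate 2 over replicate 1 after TMM scaling (x axis) for each detected member (points) of the lists with 3 or more detected genes (y axis), with an orange bar at each list's median. The medians run from -0.98 for erythroid genes to 1.09 for white blood cell genes, and epithelial and endocrine genes spread from -4.00 to 3.01.

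Reads on the strand opposite to a microRNA gene came almost entirely from loci annotated on both strands. Antisense counts made up 21.5% of sense and antisense counts together in replicate 1 and 18.8% in replicate 2. These are no shares of reads, since a read where 2 genes overlap on opposite strands enters both columns. Gm25301, for example, had 387143 antisense counts in replicate 1, the number of sense counts of Mir378a. At genes with no annotated microRNA gene on the other strand, antisense counts made up 0.00403% (Wilson 95% interval 0.00331 to 0.00490) and 0.00503% (0.00427 to 0.00593). Gm25301, annotated opposite Mir378a, had 0 sense counts in both libraries.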

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

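The tests of explanations in this part were all chosen after the results were seen. The design has 1 group, so no explanation by a difference between groups was tested for any pattern.

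Reads that map to more than 1 place lie outside the measurement and were the largest category, at 43.9% in replicate 1 and 43.2% in replicate 2. Antisense reads at genes with no annotated microRNA gene on the other strand passed 3 counts in each library at 3 genes: Mir122 with 104 such reads over the 2 libraries, Mir130a with 18 and Mirlet7b with 16. Sense reads at Mir122 numbered 81 and 63 in the 2 libraries, whereas Mirlet7b had 205471 and 276438 sense reads.

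Mir1a-1, Mir1a-2, Mir133a-1, Mir133a-2 and Mir133b were counted at low levels in heart tissue. If heart muscle cells were few, Mir499 and Mir208a were predicted to rank low among the 316 detected genes. That prediction was not met: Mir499 ranked 30 and 35 and Mir208a 53 and 58 in the 2 libraries. The lowest rank of a striated muscle gene without a shared stretch was 254. It was that of Mir206, known from skeletal muscle, so it cannot decide about heart muscle cells. A small share of heart muscle cells is still not excluded. No reference gives the level that a normal share of heart muscle cells would bring. Reads set aside because they map to several loci also remain a candidate explanation: all 5 hairpins share 20 nt or more with another locus. Mir1a-1 and Mir1a-2 are loci of 1 mature microRNA, and so are Mir133a-1 and Mir133a-2. Reads of a mature sequence that fit both loci of a pair entered no gene count, but how many there were could not be measured. A test took the fixed lists other than the Sfmbt2 and pluripotent ones, without genes overlapped by a more abundant gene. Those with a shared stretch had a median of 26.6 CPM (54 genes) against 31.7 CPM without (117 genes, two-sided permutation test, 100000 resamples, p = 0.783). That test cannot decide the matter, because a shared stretch of hairpin need not make reads fit both loci. Mir23a and Mir23b, for example, share a stretch with another locus, yet had 60975 and 64216 CPM. The multimapping reads could not be assigned to loci.

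The 2 libraries differed in 191 genes by more than counting noise. Among 198 genes with a mean of 100 counts or more, genes of the same microRNA number at unlinked loci had closer log2 ratios (median absolute difference 0.452 over 22 families) than relabelled genes (0.776; one-sided permutation test, p = 0.0159, adjusted over 2 tests 0.0159). Genes of different number within 10000 nt on 1 strand were also closer (0.456 over 23 clusters against 0.782; p = 0.0122 by the same permutation test, adjusted 0.0159). Differences tied to the mature sequence would give the first result and differences tied to the transcript the second, but neither result singles out its cause. Genes with the same mature sequence were compared only on reads that differ between their loci, since reads fitting both entered no count. Mir26a-1 and Mir26a-2, which share their mature sequence, had log2 ratios of 3.45 and -1.30. They lay outside the test because Mir26a-1, with 14 and 181 counts, missed its limit. Hairpin GC content stays open as a minor part, with a Spearman's rho of -0.0965 across detected genes (bootstrap 95% interval -0.209 to 0.0156; two-sided permutation p = 0.0880).

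Epithelial and endocrine genes differed between the libraries in both directions. Epithelial cells in replicate 2 as the source of the whole difference are argued against by 4 members that were lower there, Mir192, Mir194-1, Mir194-2 and Mir215, adjusted over the list alone. Mir194-1 lies beside Mir215 on chromosome 1 and Mir192 beside Mir194-2 on chromosome 19, so these 4 are not independent. Without these 4, an alternative chosen after seeing the data, the median log2 ratio of the other 9 detected members was 1.89, and 8 of them lay above 0. Epithelial cells that lack Mir192, Mir194 and Mir215 cannot be told apart from other sources, because these members were picked for showing the difference. The most abundant of them reached only 315 CPM (Mir203) and 263 CPM (Mir200c) in replicate 2.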

How the results depend on the processing

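The 2-fold limit and the epithelial list without Mir192, Mir194-1, Mir194-2 and Mir215 were chosen after seeing the data. Counting reads on either strand left out reads where microRNA genes overlap, Mir126a and Mir378a among them, and so moved the shares of counts to 0.705% (striated muscle), 5.76% (smooth muscle), 0.000380% (endothelial), 0.807% (fibroblast and stroma), 0.0936% (erythroid, with a median log2 ratio of -2.26) and 31.5% (let-7). Adding multimapping and ambiguous reads to the denominator lowers shares by construction, here to 0.239%, 1.94%, 4.20%, 0.270%, 0.141% and 10.9% for the same lists, 0.560% for white blood cell genes and 0.0297% for epithelial and endocrine genes. Leaving Mir378a out of the denominator gave 0.610% (striated muscle), 0.691% (fibroblast and stroma) and 27.8% (let-7), and leaving out genes with a locus number gave 0.602% for fibroblast and stroma, whose SD is very small, 0.00267% for neuronal genes, 0.896% for the miR-17-92 clusters and 3.79% for the miR-30 family. The coefficient of variation by edgeR was 0.369 at 100 counts or more, and the cause was not tested. DESeq2's 0.158 is a different measure, a median of gene-wise values where edgeR fits 1 value to all genes. Without a filter on counts DESeq2's median was 0.0001, against 0.450 by edgeR. Called genes numbered 67 with the 2-fold limit, against 191 without it, both of 316 tested. Under the alternatives fixed before the data were examined they ranged from 132 of 181 tested (100 counts or more) to 201 of 708 (no filter). The 10 most abundant genes of a single library held 65.5% to 66.6% of its counts. With n = 2 each library lies within 1 SD of a mean by construction, so leaving out a library says nothing of stability for other values. Between the libraries Mir208a over Mir208b ran from 26.9 to 72.8, Mir143 over Mir145a from 6.18 to 16.4, Mir451a over Mir144 from 1.51 to 3.15 and Mir486 over Mir3107 from 12.1 to 24.95. Shares between the libraries ran from 5.77% to 12.9% (endothelial), 0.201% to 0.424% (erythroid), 0.865% to 1.64% (white blood cell), 0.0405% to 0.0921% (epithelial and endocrine), 0.892% to 1.98% (miR-15/16), 2.03% to 3.50% (miR-29), 0.145% to 0.238% (Dlk1-Dio3) and 0.0723% to 0.117% (Sfmbt2). At 100 counts or more the median log2 ratio was -0.73 for the miR-17-92 clusters and 1.53 for epithelial and endocrine genes, and with reads on either strand it was 0.24 for neuronal genes; the cause was not tested. Of 112 named gene levels, 57 moved by over 1 SD with reads on either strand, 73 with the denominator that holds multimapping reads, 22 without Mir378a in it and 0 under the other scalings or thinning. With reads on either strand, the ratios to Mir126b, Mir3107 and Mir30e could not be given because each of these had 0 counts, Mir451a over Mir144 fell to 0, and Mir1a over Mir133a fell to 0.466, and to 8.73 with the deeper library thinned. No paired analysis was possible because there is only 1 group.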

Other observations

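The comparisons in this part were chosen after the values were seen. Outside the fixed epithelial list, log2 ratios were 3.26 for Mir182, 2.60 for Mir183, 3.33 for Mir34c, 1.49 for Mir34b and 1.26 for Mir449a, values that no test of a list stands behind. Mir205, a member of that list below the detection limit, had 5 counts in replicate 1 and 106 in replicate 2. In 2 pairs of paralogous clusters, picked by hand and not tested, Mir23a and Mir23b had 0.24 and 0.32, Mir27a and Mir27b -0.04 and -0.20, Mir24-2 and Mir24-1 -1.16 and -1.03, Mir15a and Mir15b -1.74 and -1.52, and Mir16-1 and Mir16-2 -0.85 and -0.89. Mir24-1 and Mir24-2 are loci of 1 mature microRNA, as are Mir16-1 and Mir16-2, so their ratios rest on reads that differ between the loci. Mir26a-1 and Mir26a-2, which share their mature sequence, had 14 and 181 counts for Mir26a-1 (log2 ratio 3.45) and 289 and 139 for Mir26a-2 (-1.30).

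Mir106b and Mir25 from the Mcm7 host gene were higher in replicate 1 (-1.25 and -1.51), their neighbour Mir93 had a log2 ratio of 0.12, and Mir106a and Mir20b on the X chromosome were higher in replicate 2 (2.20 and 2.08). Of the 15 lists placed among random lists, 6 lay outside the central 95%, a count without a chance level because genes of a family or cluster are not independent.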
